A study of Macaca mulatta with 22 samples.

How the data were processed

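RNA of 22 single follicles of rhesus macaques was measured on Affymetrix rhesus macaque arrays, 1 follicle per array. Per the labels' protocols, females were given a GnRH antagonist with recombinant human FSH and LH (30 IU each) when serum estradiol reached 100 to 120 pg/ml. A dose of 1000 IU of recombinant hCG set time 0, except for the 0 h follicles, which were taken without hCG. Per the labels' protocols, follicles were frozen in liquid nitrogen, total RNA was extracted with Trizol and spin columns, and 2 µg of it was amplified into biotin-labelled cRNA in the Affymetrix one-cycle protocol. Groups and replicate numbers came from the sample titles, which give the hours after hCG and, at 36 h, whether the follicle was collected before or after ovulation. Whether follicles came from separate animals is not stated for each array, so p-values measure the spread between these follicles.

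The deposited values are intensities, 1 per probe set and array, for 52865 probe sets. Per the submitters' processing notes they were made with RMA, which summarises the probes of a set after background correction and normalization between arrays. Its version is not given in the sources used here. RMA usually gives log2 values. The deposited intensities ran from 0.0361 to 15137 with array medians near 26, so they are on a linear scale and log2 was taken here, as the plan allowed for. No scan date, batch or detection call was given, so a batch could not be tested, and no probe set can be said to be above or below background. Changes of probe sets near the low end, below the arrays' median log2 of about 4.73, are uncertain in size. No 2 arrays held identical values, and the highest of 231 pairwise correlations was 0.971, between a 24 h and an unruptured 36 h follicle.

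The 99 control probe sets were left out and 52766 tested. Gene names came from the platform's annotation. Of the tested probe sets, 24956 had 1 symbol, 361 several and 27449 none in that table. Of 24969 probe sets with a single gene ID, 24629 matched the RefSeq gene table given for the macaque, which was used only for names, and 0 symbols needed an update. A gene with several probe sets is given by the brightest, the one with the highest mean over all arrays, unless said otherwise. The rule for the largest changes looked at single probe sets, so some genes it named are given by a dimmer one, which the text then says. No named gene had probe sets called in opposite directions in the comparison it is named for, though for some genes not every probe set was called.

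Group means of all 22 arrays were fitted per probe set with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), so that the groups share an estimate of the spread, since they hold only 4 to 6 arrays. Contrasts were tested two-sided, with Benjamini-Hochberg adjustment over all tested probe sets, and a probe set was called at an adjusted p under 0.05. There were 8 such results, the F test over the 5 groups, 4 comparisons of successive groups and 3 against 0 h. The 29 gene lists (pathways, regulators, cell type markers and reference genes) held 380 genes, of which 273 were measured under a single symbol. They were tested with camera at a preset correlation of 0.01 and again with an estimated one, adjusted over the lists of a comparison. A list not described for a comparison passed in neither form there. Some lists were measured in part only, so a list that did not pass says nothing on its unmeasured genes. Of 16 prostaglandin genes 5 were measured, without PTGS1, PTGS2 and PTGES, of 13 lymphocyte genes 7, and of 10 smooth muscle genes 5.

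The rule for named genes, the lists, the design and most alternatives were fixed before the data were examined. In each of the 4 successive comparisons, the rule took the 6 genes with the highest and the 6 with the lowest change among called probe sets with a single, non-placeholder symbol whose groups did not overlap. It also took up to 2 called members per list and comparison with the largest absolute change, and a panel of 14 genes given whatever the test showed. Genes given against 0 h (among them PER1 and TOP2A) and those of the lists added later lie outside the rule and were chosen after their values were seen.

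The fit was tested on simulated data with the real arrays' means and spread, where 100 brighter probe sets were changed 2-fold and 100 changed 4-fold. For 12 h against 0 h it recovered 67% and 93% of them, for 24 h against 12 h 49% and 90%, for unruptured 36 h against 24 h 52% and 85%, and for ruptured against unruptured follicles 62% and 97%. Among the unchanged probe sets it called 12, 6, 10 and 5 in the same order of comparisons. The camera step, simulated for 12 h against 0 h, called 1 of 1 shifted list and 0 of 28 unshifted lists. The simulated genes varied independently, so this does not check camera for lists whose genes vary together. Genes called in opposite directions in the first 2 steps were counted beside 20 simulated unchanged data sets and with the 12 h arrays split.

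Alternatives tried were array medians subtracted, quantile normalization repeated, only the brighter probe sets, trend and robust moderation, array weights, 1 probe set per gene, a 2-fold minimum, the replicate number as a block, only the 2 groups compared, each array left out in turn and, for the last interval, all 36 h follicles together. Added after seeing the data were log2 of intensity plus 16 and the 3' minus 5' index as a covariate. This index is the mean over the actin, GAPDH and EF1A control transcripts of the 3' minus the 5' probe set value, a sign of RNA degradation. Up to 100 splits of the arrays into groups of the same sizes were refitted per result.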

Results

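Gene expression was measured in single follicles of rhesus macaques (Macaca mulatta) around ovulation. The dominant follicle, the one that outgrows the others in a menstrual cycle, was taken before and at set times after human chorionic gonadotropin (hCG), a hormone that acts on the luteinizing hormone receptor and sets off ovulation. The 22 arrays, each from 1 follicle, fell into 5 groups. There were 6 follicles at 0 h (no hCG), 4 at 12 h, 4 at 24 h, 4 at 36 h that had not ruptured and 4 at 36 h that had ruptured. Sample titles call all samples ovulatory follicles, while most descriptions speak of developing corpus luteum, the gland that forms from the follicle after ovulation. They are called follicles here. The values were array intensities, with a median of 26.1 to 26.7 per array, and all values below are log2 intensities, on which a change of 1 is a 2-fold change. The number of arrays limits the precision. Changes are given with their standard error (SE), levels with their standard deviation (SD).

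The question set by the design was how the follicle's transcripts change over the interval from the ovulatory stimulus to rupture. Of 52766 probe sets, 10626 (20.1%) differed between the 5 groups in limma's moderated F test, and 16791 had an unadjusted p under 0.05. The first principal component of the brighter probe sets held 26.5% of the variance. On it the 12 h arrays (mean score 36.5 ± 11.1 SD, n = 4) and the ruptured follicles (59.6 ± 3.0, n = 4) had positive means, and the 0 h (-40.0 ± 9.3, n = 6), 24 h (-15.1 ± 13.6, n = 4) and unruptured 36 h follicles (-21.2 ± 5.2, n = 4) negative ones. Of these last 3 groups, 24 h replicate 4 alone had a positive score, 5.34. The second component held 14.2%, and its mean was 31.7 ± 7.5 at 0 h, 21.7 ± 13.9 at 12 h, -30.3 ± 4.4 at 24 h, -35.2 ± 3.8 in unruptured and -3.7 ± 9.0 in ruptured follicles.

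A panel of genes of ovarian function was fixed before the data were examined, and 9 of its 14 genes carried a name in the annotation used here. STAR, which moves cholesterol into mitochondria for steroid synthesis, had a mean of 12.41 ± 0.24 (SD, n = 6) at 0 h, 13.22 ± 0.28 (n = 4) at 12 h, 13.18 ± 0.07 at 24 h, 13.05 ± 0.16 in unruptured and 13.35 ± 0.03 in ruptured follicles. HSD3B2, the enzyme that makes progesterone from pregnenolone, was at 11.01 ± 0.64, 11.92 ± 0.54, 9.83 ± 0.91, 8.46 ± 0.49 and 12.09 ± 0.26 in the same order of groups. CYP17A1, needed for androgen synthesis, was at 12.05 ± 0.40, 10.16 ± 1.09, 7.82 ± 0.57, 7.55 ± 0.34 and 7.24 ± 0.39. CYP19A1, the aromatase that makes estrogen, was at 11.34 ± 0.85, 10.12 ± 0.93, 6.96 ± 1.04, 5.97 ± 0.77 and 7.41 ± 1.23. The progesterone receptor gene PGR was at 6.15 ± 0.26, 7.62 ± 1.40, 5.93 ± 0.09, 5.63 ± 0.28 and 6.20 ± 0.31. AREG, which codes for the EGF-like ligand amphiregulin, was at 2.69 ± 1.94, 10.13 ± 1.01, 7.13 ± 1.20, 8.09 ± 1.53 and 12.30 ± 0.16. The protease gene ADAMTS1 was at 9.30 ± 0.38, 10.03 ± 0.29, 10.11 ± 0.12, 10.17 ± 0.49 and 11.38 ± 0.85. The hyaluronan synthase gene HAS2 was at 2.74 ± 0.67, 5.14 ± 1.11, 3.09 ± 1.93, 3.74 ± 0.59 and 6.20 ± 0.78. The proliferation marker MKI67 was at 7.17 ± 0.34, 5.77 ± 0.72, 6.13 ± 0.27, 6.10 ± 0.37 and 6.17 ± 0.61. CYP11A1, LHCGR, FSHR, PTGS2 and VEGFA were not analysed here.

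**Figure D1:**
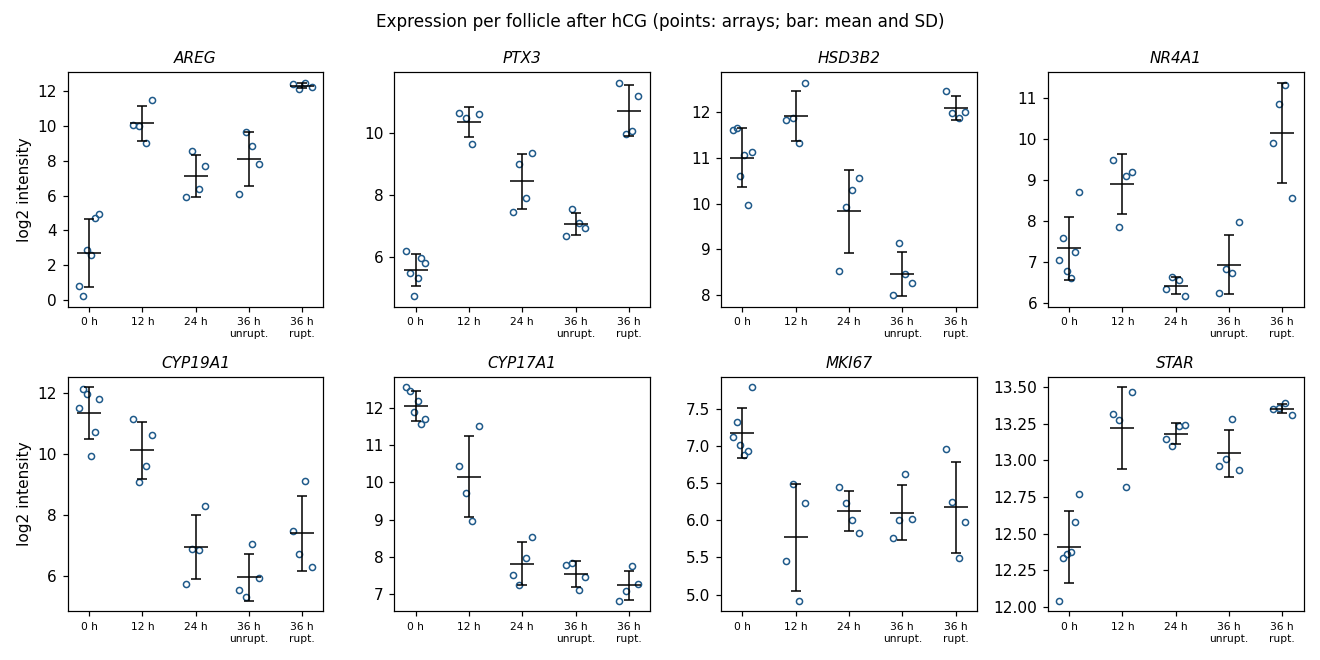
Log2 intensity of 8 genes in each follicle (points) with the group mean and SD (bars), by group along the x axis; each panel has its own y scale, which does not start at 0. AREG, PTX3, HSD3B2 and NR4A1 had lower means at 24 h and in unruptured 36 h follicles than at 12 h and in ruptured follicles; all 4 ruptured follicles were at or above 12.1 for AREG, while unruptured ones reached at most 9.64.

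In the first 12 h after hCG, AREG rose by a log2 change of 7.44 ± 0.87 (SE, adjusted p = 3.55e-05), the highest of any named gene. It started near the lower end of the array's range, so the size of its change is uncertain. SERPINA3, an antiprotease gene, rose by 6.48 ± 0.32 (adjusted p = 2.58e-09), MYH4 by 6.49 ± 0.84 and CYP3A5 by 4.89 ± 0.81. Among matrix proteolysis genes, 8 of 18 measured members rose and 2 fell (9 and 3 adjusted over the list alone), with a median log2 change of 0.91. The collagenase gene MMP1 rose by 5.30 ± 0.58 (adjusted p = 2.03e-05) and the stromelysin gene MMP10 by 4.98 ± 0.83 (adjusted p = 0.000869). Of 9 cumulus matrix genes, which build the hyaluronan coat around the oocyte, 4 rose and 0 fell (5 and 0 adjusted over the list alone), with a median of 0.96. PTX3 rose by 4.73 ± 0.40 (adjusted p = 1.71e-06) and TNFAIP6 by 3.52 ± 0.58 (adjusted p = 0.000829). Both lists passed the camera gene set test with its preset correlation, with adjusted p = 0.000666 and 0.00249, and not with an estimated one, with adjusted p = 0.08 for each.

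Of the 14 gonadotropin-induced transcription factor genes, 7 rose and 0 fell (11 and 1 adjusted over the list alone), with a median of 1.13 (camera adjusted p = 8.91e-06, or adjusted p = 0.2 with an estimated correlation). CEBPB rose by 1.93 ± 0.20 (adjusted p = 1.11e-05) and JUNB by 1.86 ± 0.40 (adjusted p = 0.00547). Of 16 cytokine and chemokine genes 6 rose and 1 fell (7 and 1 adjusted over the list alone), with a median of 0.53 (adjusted p = 0.00626, or adjusted p = 0.2 with an estimated correlation). LIF rose by 2.83 ± 0.50 (adjusted p = 0.00143) and CCL2, which attracts monocytes, by 2.63 ± 0.41 (adjusted p = 5e-04). Macrophage and monocyte marker genes moved with these lists, with 4 of 11 higher and 0 lower (7 and 0 adjusted over the list alone) and a median of 0.80 (adjusted p = 0.000903, or adjusted p = 0.319 with an estimated correlation). TYROBP rose by 1.66 ± 0.39 and AIF1 by 1.33 ± 0.31. Of 8 genes of the unfolded protein response 6 rose and 0 fell (also 6 and 0 adjusted over the list alone), among them SDF2L1 by 1.16 ± 0.27 (list adjusted p = 0.000911, or adjusted p = 0.0846 with an estimated correlation). Single members of other lists rose too. HSD11B1, which regenerates active glucocorticoid, rose by 3.93 ± 0.53 (adjusted p = 0.000141). The cAMP feedback gene RGS2 rose by 2.21 ± 0.32, the prostaglandin-degrading HPGD by 1.62 ± 0.37, DHCR7 of cholesterol synthesis by 1.99 ± 0.41, the neutrophil and monocyte marker FCN1 by 2.33 ± 0.40. The cell cycle inhibitor CDKN1A rose by 1.11 ± 0.25, SERPINF1 by 1.19 ± 0.19, the glucose transporter gene SLC2A1 by 0.99 ± 0.23, HBEGF by 1.17 ± 0.26 and TAGLN by 0.50 ± 0.12.

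Cell cycle genes fell at 12 h in 12 of 15 measured cases and rose in 0 (14 and 0 adjusted over the list alone), with a median log2 change of -0.77 (camera adjusted p = 9.86e-10, or adjusted p = 0.104 with an estimated correlation). MKI67 changed by -1.40 ± 0.30 (adjusted p = 0.00606) and CCNB2 by -1.21 ± 0.25 (adjusted p = 0.00379). Of 9 antral granulosa genes 3 fell and 0 rose (5 and 0 adjusted over the list alone), with a median of -1.36 (adjusted p = 0.00865, or adjusted p = 0.21 with an estimated correlation). INHBB, an inhibin and activin subunit gene, changed by -3.84 ± 0.76 and HSD17B1, which makes estradiol, by -1.96 ± 0.36. Androgen and estrogen synthesis had 3 lower and 1 higher of 6 (3 and 2 adjusted over the list alone), with CYP17A1 at -1.90 ± 0.38 (adjusted p = 0.00326). CYP19A1 did not pass the test, with -1.22 ± 0.60 (adjusted p = 0.246). Progesterone synthesis was split, with 1 gene up and 3 down of 9 (3 and 4 adjusted over the list alone). STAR rose by 0.81 ± 0.14 (adjusted p = 0.00101), while NR5A1, a transcription factor of steroidogenic genes, changed by -1.62 ± 0.21 and FDXR by -1.46 ± 0.30. PGRMC1 fell by 1.29 on the log2 scale (SE 0.12), and PRKAR2B (-1.04 ± 0.18), PROK1 (-1.63 ± 0.36), OGN (-1.14 ± 0.23), HHIP (-1.16 ± 0.24) and the dim CDH1 (-3.19 ± 0.63) fell as well. The lowest changes outside the lists were those of CNNM2 (-3.92 ± 0.83), PAK5 (-3.84 ± 0.86, but -1.73 ± 0.29 in its brightest probe set), RDM1 (-3.65 ± 0.77), MAP6D1 (-3.33 ± 0.40) and TNNI3 (-3.30 ± 0.65). Of the reference genes, SDHA changed by -0.75 ± 0.14 and HPRT1 by 0.68 ± 0.12.

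In all, 4922 probe sets passed the test between 12 h and 0 h, 2259 higher and 2663 lower at 12 h, and 1724 of them by at least 2-fold (870 higher, 854 lower). The 8 lists given above with a camera p passed at the preset correlation and none of the 29 did with an estimated one. The other 21 had preset adjusted p from 0.0603 (cholesterol synthesis and uptake, 3 of 13 up, 4 adjusted over the list alone) to 0.954 (EGF-like ligands and receptors, where the median of -0.34 and the mean of 0.59 had opposite signs). Hypoxia and glycolysis genes also had a median of -0.14 and a mean of 0.04. A fit of only these 2 groups called 2740 probe sets. The 3' minus 5' index of the control transcripts, a sign of RNA quality, was 0.391 ± 0.079 (SD, n = 4) at 12 h and 0.328 ± 0.041 (n = 6) at 0 h. Among the 12 h arrays, replicate 3 had 0.506 and the others 0.331 to 0.371. With this index as a covariate 3388 probe sets were called, and 65.7% of the 4922 stayed in the same direction, with a median size of 0.81 (from 0.83) and a median SE of 0.20 (from 0.18). With it 4 named genes lost their calls while each change moved by less than its SE and each SE widened. They were AIF1 (1.13 ± 0.33 SE, from 1.33 ± 0.31), DDIT3 (0.52 ± 0.18, from 0.63 ± 0.17), GADD45B (1.42 ± 0.43, from 1.38 ± 0.39) and HAS2 (2.43 ± 0.76, from 2.39 ± 0.67). Calls on 7 of the 53 named genes ended when an array was left out. HAS2 (2.39 ± 0.67) lost its call without 0 h replicate 3 or 4 or 12 h replicate 2 or 4 (adjusted p up to 0.123). GADD45B (1.38 ± 0.39) lost it without 0 h replicate 3 or 5 or 12 h replicate 2 or 3 (up to 0.0869). DDIT3 (0.63 ± 0.17) lost it without 0 h replicate 5 or 12 h replicate 1 or 3 (up to 0.0929). PPBP (1.90 ± 0.50) lost it without 12 h replicate 1, 2 or 4 (up to 0.0618). PGR (1.47 ± 0.40) lost it without 12 h replicate 1 (adjusted p = 0.0596). CYP51A1 (1.23 ± 0.29) lost it without 12 h replicate 4 (adjusted p = 0.0509). CA9 (-1.10 ± 0.28) lost it without 12 h replicate 2 (adjusted p = 0.0635).

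Between 12 h and 24 h many of these changes turned around. Of the 9 cumulus matrix genes 3 fell and 0 rose (5 and 0 adjusted over the list alone), with a median of -0.95 (camera adjusted p = 0.0138, or adjusted p = 0.222 with an estimated correlation, and adjusted p = 0.0506 without 12 h replicate 4). PTX3 changed by -1.90 ± 0.43 (adjusted p = 0.0117) and HAS1 by -2.53 ± 0.75 (adjusted p = 0.0495). Of the 14 gonadotropin-induced transcription factor genes 6 fell and 0 rose (7 and 0 adjusted over the list alone), with a median of -0.83 (adjusted p = 0.00685, or adjusted p = 0.746 with an estimated correlation). The immediate early gene NR4A1 changed by -2.49 ± 0.54 (adjusted p = 0.00857) and JUNB by -1.83 ± 0.44 (adjusted p = 0.015). The cytokine genes LIF (-2.92 ± 0.55, adjusted p = 0.0033) and CCL2 (-2.79 ± 0.45, adjusted p = 0.00108) fell, with 3 of 16 list members down and 0 up, the same numbers when adjusted over the list alone. The protease gene ADAMTS4 changed by -2.72 ± 0.46 (adjusted p = 0.00149), in a proteolysis list with 3 members up and 3 down (4 and 4 adjusted over the list alone). Glycolysis genes SLC2A1 (-1.26 ± 0.25) and HK2 (-1.22 ± 0.27) were among 4 of 14 hypoxia and glycolysis genes that fell (also 4 adjusted over the list alone, with 1 higher).

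CYP19A1, CYP17A1 and HSD3B2 of steroid synthesis fell from 12 h to 24 h, while neither steroid synthesis list passed camera (adjusted p = 0.42 and 0.867). CYP19A1 changed by -3.16 ± 0.66 (adjusted p = 0.00637), CYP17A1 by -2.33 ± 0.41 (adjusted p = 0.00212) and HSD3B2 by -2.10 ± 0.42 (adjusted p = 0.00504), while TSPO rose by 1.06 ± 0.21. INHBA, the other activin subunit gene, changed by -2.38 ± 0.46 (adjusted p = 0.00374) and HBEGF by -1.29 ± 0.28. Glucocorticoid-responsive TSC22D3 rose by 1.25 ± 0.17 (adjusted p = 0.000311) and ZBTB16 by 1.17 ± 0.25 (adjusted p = 0.00821), with 2 of 6 list genes up, and 3 of 6 when adjusted over the list alone. Of the cell cycle genes 0 of 15 passed in either direction. The chaperone gene HSP90B1 changed by -0.67 ± 0.12 and the oocyte gene ZP4 by -0.69 ± 0.15. The reference gene HPRT1 changed by -0.80 ± 0.13. Outside the lists the highest changes were in CCDC110 (3.49 ± 0.77), ADD3 (3.36 ± 0.81, but 0.60 ± 0.18 in its brightest probe set), ACSM3 (3.20 ± 0.28, but 1.92 ± 0.31 in its brightest), ASPA (3.05 ± 0.71), MTTP (3.05 ± 0.68) and PMEL (2.89 ± 0.57). The lowest were in CYP3A5 (-4.77 ± 0.88), in UBASH3B (-3.23 ± 0.64, but -1.44 ± 0.39 in its brightest probe set), in a dimmer CD8B probe set (-3.15 ± 0.83) and in a second NR4A1 probe set (-2.98 ± 0.62). The brightest CD8B probe set, at 0.25 ± 0.70, was not called (adjusted p = 0.899).

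At 24 h 1937 probe sets were higher than at 12 h and 1691 lower, 3628 in all, of which 1181 by at least 2-fold. This count was 189 in a fit of only these 2 groups, 2195 with the 3' minus 5' index as a covariate, 2265 without 12 h replicate 1 and 2199 without 24 h replicate 1. Apart from cumulus matrix and transcription factor genes, no fixed list passed camera (adjusted p from 0.0701 to 0.937), and none did with an estimated correlation. Antral granulosa genes had a median of 0.44, a mean of -0.35 and a downward test, EGF-like genes a median of 0.48, a mean of -0.08 and an upward test, theca genes a median of 0.09, a mean of -0.22 and a downward test, receptor genes a median of 0.15, a mean of -0.07 and an upward test, and oocyte genes a median of 0.18, a mean of 0.14 and a downward test. With the index, 11 named genes lost their calls while each change moved by less than its SE and each SE widened. They had changes of -2.70 ± 0.96 (CD8B), 2.71 ± 0.82 (CDH1), -2.62 ± 0.89 (HAS1), 0.79 ± 0.30 (HHIP), -1.45 ± 0.47 (HPGD), -2.13 ± 0.70 (KRT8), -1.75 ± 0.72 (MMP1), 2.51 ± 0.76 (MTTP), -1.81 ± 0.51 (PTX3), -2.04 ± 0.66 (ROBO4) and -0.42 ± 0.13 (XBP1). PTX3 without the index was at -1.90 ± 0.43 and HAS1 at -2.53 ± 0.75. MMP1 also lost its call with array weights. With 16 added to the intensities before the logarithm, HAS1, ROBO4 and CDH1 lost theirs and their changes shrank to -1.25, -0.72 and 0.45 (adjusted p = 0.149, 0.05 and 0.119), so their sizes depend on this choice. Calls on 16 of the 40 named genes ended when an array was left out. HAS1 lost its call without any array of the 2 groups but 24 h replicate 2 (adjusted p up to 0.126). MMP1 (-2.17 ± 0.64) lost it without 12 h replicate 1, 3 or 4 or 24 h replicate 1 or 2 (up to 0.152). DUSP1 (-1.27 ± 0.35) lost it without any but 12 h replicate 3 and 24 h replicate 4 (up to 0.126). ROBO4 (-1.95 ± 0.56) lost it without any but 12 h replicate 3 and 24 h replicate 2 (up to 0.124). CDH1 (2.58 ± 0.69) lost it without 12 h replicate 2, 3 or 4 or 24 h replicate 1 or 4 (up to 0.107). HHIP (0.95 ± 0.26) lost it without any but 12 h replicate 4 and 24 h replicate 4 (up to 0.0899). OGN (0.99 ± 0.25) lost it without any but 12 h replicate 3 and 24 h replicate 4 (up to 0.0859). XBP1 (-0.43 ± 0.11) lost it without 12 h replicate 1 or 4 or 24 h replicate 1, 2 or 3 (up to 0.092). CD8B lost it without 12 h replicate 2 or 3 or 24 h replicate 1 or 4 (up to 0.0793). SQLE (-1.27 ± 0.32) lost it without 12 h replicate 1 or 4 or 24 h replicate 1 (up to 0.0829). KRT8 (-2.38 ± 0.61) lost it without 12 h replicate 1, 3 or 4 (up to 0.0596). HPGD (-1.63 ± 0.40) lost it without 12 h replicate 4 or 24 h replicate 2 (up to 0.0684). PGR (-1.70 ± 0.43) lost it without 12 h replicate 1 or 24 h replicate 1 (up to 0.0575). JUNB lost it without 12 h replicate 1 (adjusted p = 0.0525). ADD3 lost it without 12 h replicate 4 (adjusted p = 0.0594). PTX3 lost it without 24 h replicate 1 (adjusted p = 0.0501).

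The first 2 steps often opposed each other in the same probe set. Of the probe sets called higher at 12 h, 794 (35.1%) were called lower again at 24 h, and 1031 (38.7%) of those called lower at 12 h were called higher at 24 h. Independent lists of these sizes would share 72.4 and 97.8. Both steps use the 12 h arrays, with opposite sign. Simulated groups with no change gave a mean of 0 and 0. These simulated groups held no changed probe sets, so they cannot show how much the shared 12 h arrays add to the counts. With the 12 h arrays split, 2 to each step, the median counts over 6 splits were 202 (175 to 239) and 255.5 (232 to 295). Only 4 probe sets rose at both steps and 8 fell at both.

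From 24 h to the unruptured follicles at 36 h, SERPINA3 was the only gene with a call, and 2 of its 5 probe sets gave it. It fell from 11.26 ± 0.49 to 8.60 ± 0.70 (SD, n = 4 each), a log2 change of -2.67 ± 0.36 (adjusted p = 0.0255). This was 2 of 52766 probe sets in limma. An unadjusted p under 0.05 was seen in 3298, where chance alone would give a share of about 0.05 of all tested. HSD3B2 had a change of -1.37 ± 0.42 (adjusted p = 0.629), CYP19A1 of -0.99 ± 0.66 (adjusted p = 0.859) and AREG of 0.96 ± 0.95 (adjusted p = 0.923), and none of these passed the test. Endothelial marker genes, with a median of 0.36 and 0 of 10 members called (1 higher adjusted over the list alone), passed camera at the preset correlation (adjusted p = 0.00322), but with an estimated one had adjusted p = 0.688. That list also missed the threshold without 24 h replicate 1 (adjusted p = 0.197) or unruptured replicate 1 (adjusted p = 0.0614). The SERPINA3 call ended without 24 h replicate 2, 3 or 4 or unruptured replicate 3 (adjusted p up to 0.181). With the 3' minus 5' index as a covariate SERPINA3 changed by -2.66 ± 0.37 (adjusted p = 0.0668), so the call ended with the change as large and a wider SE. Without 1 array the number of calls ran from 0 to 5, and with the 8 follicles of 36 h taken as 1 group 0 probe sets were called. In simulated data for this comparison 52 of 100 brighter probe sets changed 2-fold and 85 of 100 changed 4-fold were recovered.

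Ruptured follicles differed from unruptured ones at the same 36 h in many of the genes that had moved at 12 h. Of 9 measured cumulus matrix genes 5 rose and 0 fell (also 5 and 0 adjusted over the list alone), with a median of 1.39. This list passed camera with the preset (adjusted p = 0.000289) and with an estimated correlation (adjusted p = 0.0397). HAS1 rose by 3.76 ± 0.75 (adjusted p = 0.00351) and PTX3 by 3.63 ± 0.43 (adjusted p = 5.94e-05). AREG rose by 4.20 ± 0.95 (adjusted p = 0.00795) and HBEGF by 2.00 ± 0.28 (adjusted p = 0.000249). Of 18 matrix proteolysis genes 7 rose and 2 fell (8 and 3 adjusted over the list alone), with MMP1 up by 4.50 ± 0.64 (adjusted p = 0.000233) and ADAMTS4 by 4.09 ± 0.46 (adjusted p = 3.4e-05); the list had a median of 0.31 (adjusted p = 0.00696, or adjusted p = 0.175 with an estimated correlation). LIF rose by 4.71 ± 0.55 (adjusted p = 4.98e-05) and CCL2 by 3.12 ± 0.45 (adjusted p = 0.000268), while the cytokine list as a whole, with 3 up and 1 down of 16 (6 and 2 adjusted over the list alone), did not pass (adjusted p = 0.0958). The other genes with the highest changes were the stromelysin gene MMP3 (4.88 ± 0.86), the phosphatase gene DUSP5 (4.72 ± 0.93), the BMP inhibitor gene CHRDL2 (4.72 ± 0.56) and NPPC (4.60 ± 0.42), which codes for a natriuretic peptide that holds the oocyte in meiotic arrest. NPPC was at 1.37 ± 0.34 in unruptured and 5.97 ± 0.74 in ruptured follicles.

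Gonadotropin-induced transcription factor genes rose in 8 of 14 cases and fell in 0 (10 and 0 adjusted over the list alone), with a median of 1.45 (camera adjusted p = 6.16e-06, or adjusted p = 0.18 with an estimated correlation). NR4A1 rose by 3.21 ± 0.54 (adjusted p = 0.000888) and EGR2 by 2.57 ± 0.58 (adjusted p = 0.00839). Of 12 cAMP feedback genes 5 rose and 0 fell (also 5 and 0 adjusted over the list alone), DUSP1 by 1.84 ± 0.35 (adjusted p = 0.0026) and SIK1 by 2.17 ± 0.54, with a median of 0.72 (adjusted p = 0.00438, or adjusted p = 0.18 with an estimated correlation). Progesterone synthesis genes rose in 3 of 9 cases and fell in 0 (4 and 0 adjusted over the list alone), with a median of 0.34. HSD3B2 rose by 3.63 ± 0.42 (adjusted p = 4.48e-05) and the electron carrier gene FDX1 by 1.21 ± 0.20 (adjusted p = 0.000724), and the list passed camera (adjusted p = 0.00386, or adjusted p = 0.316 with an estimated correlation). Of 13 genes of cholesterol synthesis and uptake 6 rose and 0 fell (8 and 0 adjusted over the list alone), with a median of 0.72 (adjusted p = 0.000198, or adjusted p = 0.25 with an estimated correlation), SQLE by 1.72 ± 0.32 and DHCR7 by 1.83 ± 0.45. CYP17A1 (-0.30 ± 0.41, adjusted p = 0.741) and CYP19A1 (1.44 ± 0.66, adjusted p = 0.198) did not pass. Hypoxia and glycolysis genes rose in 6 of 14 cases and fell in 1 (7 and 1 adjusted over the list alone), with SLC2A3 up by 1.61 ± 0.21 and SLC2A1 by 1.18 ± 0.25 (list adjusted p = 0.00386, or adjusted p = 0.175 with an estimated correlation). Unfolded protein response genes rose in 3 of 8 cases and fell in 0 (also 3 and 0 adjusted over the list alone), XBP1 by 0.69 ± 0.11 and HSP90B1 by 0.67 ± 0.12 (list adjusted p = 0.00438, or adjusted p = 0.175 with an estimated correlation). INHBA rose by 3.20 ± 0.46 (adjusted p = 0.000245), FGF2 by 1.93 ± 0.38, ESR2 by 1.63 ± 0.37, BTG2 by 1.66 ± 0.39 and the reference gene HPRT1 by 1.05 ± 0.13.

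Lower in ruptured follicles were the glucocorticoid-responsive genes ZBTB16 (-1.21 ± 0.25, adjusted p = 0.00466) and TSC22D3 (-0.97 ± 0.17, adjusted p = 0.00117). Cell cycle genes had a median of -0.37 with 1 of 15 called lower, 4 adjusted over the list alone (camera adjusted p = 0.0236, or adjusted p = 0.609 with an estimated correlation). That list missed the threshold without unruptured replicate 3 (adjusted p = 0.0558) or ruptured replicate 8 (adjusted p = 0.128). The lowest single changes were those of CEP250 (from 3.61 ± 0.51 SD to -0.39 ± 0.23, n = 4 each) and, as log2 changes with SE, KLHDC1 (-3.27 ± 0.56), RILPL2 (-2.81 ± 0.78), CCDC110 (-2.64 ± 0.77), ANKS1B (-2.62 ± 0.45) and MINAR1 (-2.48 ± 0.50). Those of CEP250, KLHDC1, RILPL2 and ANKS1B are not from the gene's brightest probe set, which changed by -1.29 ± 0.23 for KLHDC1 and -0.71 ± 0.13 for RILPL2 and was not called for CEP250 (adjusted p = 0.0817) and ANKS1B (adjusted p = 0.684). Of the cell type lists, macrophage and monocyte markers had a median of -0.17 with 0 of 11 called, endothelial markers of -0.08 with 0 of 10 and oocyte genes of -0.65 with 1 of 11 called, ZP4, which was higher, each with a camera adjusted p of 0.765. The mean of the oocyte genes was 4.426 in ruptured replicate 8, against 4.963 to 5.558 in the other ruptured arrays. It was also low in 0 h replicate 2 (3.863, others 5.535 to 6.236) and 24 h replicate 4 (4.066, others 5.163 to 5.907). Glucocorticoid genes had a median of 0.07 and a mean of -0.04, and EGF-like genes a median of -0.04 and a mean of 0.48.

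In total 2549 probe sets were higher and 2632 lower in ruptured follicles, 5181 in all and 1852 by at least 2-fold; among these 1194 were higher and 658 lower. The fit of only these 2 groups called 1318. RILPL2 lost its call with 16 added to the intensities before the logarithm, where its change shrank to -0.43 (adjusted p = 0.104). Calls on 14 of the 47 named genes ended when an array was left out. HAS2 (2.46 ± 0.74) lost its call without any array of the 2 groups but ruptured replicate 8 (adjusted p up to 0.104). ADAMTS1 (1.21 ± 0.33) lost it without unruptured replicate 1, 2 or 3 or ruptured replicate 6 or 7 (up to 0.094). AMHR2 (-0.94 ± 0.27) lost it without unruptured replicate 2 or 4 or ruptured replicate 5, 6 or 7 (up to 0.107). HSD17B7 (1.30 ± 0.37) lost it without unruptured replicate 1 or 4 or ruptured replicate 5, 6 or 7 (up to 0.101). KRT18 (-0.75 ± 0.21) lost it without unruptured replicate 3 or 4 or ruptured replicate 5, 6 or 8 (up to 0.0872). ANGPT1 (-1.12 ± 0.31) lost it without any but unruptured replicate 4 and ruptured replicate 7 (up to 0.075). RILPL2 lost it without any but unruptured replicate 2 and ruptured replicate 8 (up to 0.0803). CCDC110 lost it without any unruptured array or ruptured replicate 5 or 8 (up to 0.103). MCM5 (-0.57 ± 0.16) lost it without unruptured replicate 2 or 4 or ruptured replicate 6 (up to 0.0852). HSD17B4 (-0.63 ± 0.16) lost it without unruptured replicate 2 or ruptured replicate 5 (up to 0.0636). CDKN1A (1.11 ± 0.28) lost it without unruptured replicate 1 or ruptured replicate 7 (up to 0.0617). DHCR7 lost it without unruptured replicate 1 (adjusted p = 0.0513). SIK1 lost it without ruptured replicate 7 (adjusted p = 0.0535). ZP4 (0.59 ± 0.15) lost it without ruptured replicate 5 (adjusted p = 0.0511).

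**Figure D2:**
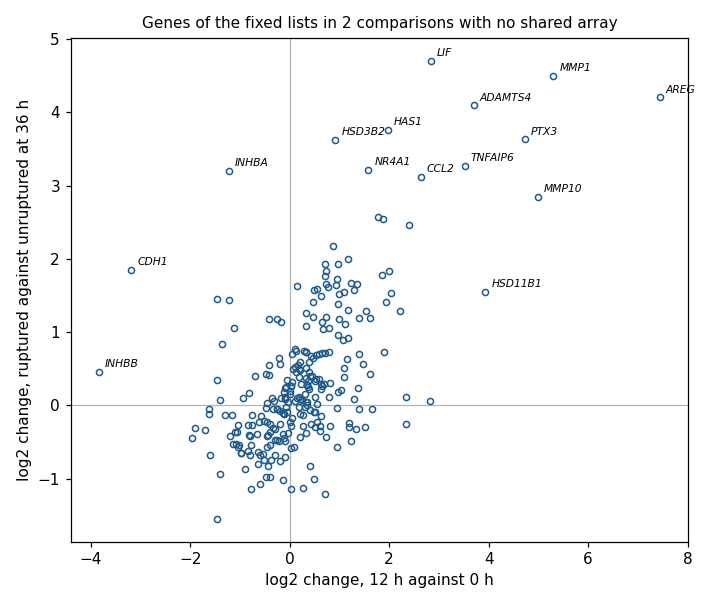
Log2 change of the 273 measured genes of the fixed lists at 12 h against 0 h (x axis) and in ruptured against unruptured follicles at 36 h (y axis), 1 point per gene. Of the 90 called at 12 h, 76 had the same sign in the second comparison; LIF, MMP1, ADAMTS4, AREG and PTX3 lie far from 0 on both axes.

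The 12 h changes and those at rupture were set against each other, since they share no array. Both come from 1 fit and share each probe set's estimate of the spread. This can raise the overlap above that of independent lists, in either direction. Of the 4922 probe sets called at 12 h, 88.7% changed in the same direction in ruptured against unruptured follicles, with a median change of 0.52 signed by the 12 h direction. Called in both, in the same direction, were 1020 higher and 958 lower probe sets, where independent lists of these sizes would share 109.1 and 132.8, and 19 were called in opposite directions, where 241.3 would be. Across the brighter probe sets the correlation of the changes was 0.56, and 0.28 across all, over probe sets that are not independent replicates. The same 12 h probe sets had a median signed change of -0.55 from 12 h to 24 h, which share the 12 h arrays, and of -0.07 from 24 h to unruptured 36 h.

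Against 0 h, CYP19A1, CYP17A1 and genes of the cell cycle were lower at 24 h and 36 h, and genes of glucocorticoid metabolism and response were higher. CYP19A1 changed by -4.38 ± 0.60 at 24 h, -5.37 ± 0.60 in unruptured and -3.93 ± 0.60 in ruptured follicles. CYP17A1 changed by -4.23 ± 0.38, -4.50 ± 0.38 and -4.81 ± 0.38, and TOP2A, which is made in dividing cells, by -1.73 ± 0.28 at 24 h and -1.64 ± 0.28 in unruptured follicles. Of 15 cell cycle genes 10, 11 and 15 fell in these 3 comparisons and 0 rose (15, 14 and 15 adjusted over the list alone), and the list passed camera with an estimated correlation in each (adjusted p = 0.0306, 0.0365 and 0.0484). Of 6 glucocorticoid genes 5, 4 and 3 rose and 0 fell (5, 5 and 3 adjusted over the list alone), also with an estimated correlation (adjusted p = 0.0048, 0.00467 and 0.0484). HSD11B1 rose by 5.46 ± 0.53 at 24 h, 4.88 ± 0.53 in unruptured and 6.43 ± 0.53 in ruptured follicles, and PER1, a clock gene that also responds to glucocorticoid, by 1.06 ± 0.28, 1.16 ± 0.28 and 1.17 ± 0.28. Matrix proteolysis genes passed as well (adjusted p = 0.0115, 0.0365 and 0.0189 with an estimated correlation), with 4, 5 and 9 of 18 up and 0, 1 and 3 down (9, 8 and 11 up and 1, 1 and 3 down adjusted over the list alone). In ruptured follicles against 0 h AREG was higher by 9.60 ± 0.87, and cumulus matrix genes (5 of 9 up, also 5 adjusted over the list alone, adjusted p = 0.0189) and gonadotropin-induced transcription factors (11 of 14 up, 12 adjusted over the list alone, adjusted p = 0.0487) passed with an estimated correlation. Neutrophil markers had 1, 1 and 4 of 9 members higher (2, 5 and 4 adjusted over the list alone), FCN1 among them, passed camera at the preset correlation (adjusted p = 0.0113, 0.00757 and 0.00712) and missed the threshold with an estimated correlation (adjusted p = 0.183, 0.101 and 0.104). Progesterone synthesis genes were mostly lower at 24 h (2 up and 5 down of 9) and in unruptured follicles (2 up and 6 down), with medians of -1.02 and -1.10 (adjusted p = 0.00221 and 0.00127, or adjusted p = 0.288 and 0.238 with an estimated correlation). In ruptured follicles their median was -0.08 with 3 up and 2 down (adjusted p = 0.687).

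Other lists passed camera against 0 h. Angiogenic factors rose in 3 of 14 cases in unruptured and 5 in ruptured follicles (5 and 7 adjusted over the list alone), with adjusted p = 0.0457 and 0.0484 with an estimated correlation. Unfolded protein response genes rose in 5 of 8 cases in ruptured follicles (6 adjusted over the list alone, adjusted p = 0.0484 with an estimated correlation). The rest passed at the preset correlation only. At 24 h these were antral granulosa genes (median -1.26, adjusted p = 0.0689 with an estimated correlation) and macrophage and monocyte markers (median 0.63, adjusted p = 0.439 with an estimated correlation). In unruptured follicles they were androgen and estrogen synthesis (median -0.69), antral granulosa (-1.31) and theca genes (-0.52), with adjusted p = 0.0568, 0.0672 and 0.0672 with an estimated correlation. Also there, they were gonadotropin-induced transcription factors (median 0.54), endothelial (0.62), smooth muscle (0.26) and macrophage markers (0.41), with adjusted p = 0.394, 0.22, 0.394 and 0.54 with an estimated correlation. In ruptured follicles they were cholesterol synthesis (median 0.94), cAMP feedback (0.42), cytokine (0.73) and endothelial genes (0.51), with adjusted p = 0.222, 0.216, 0.109 and 0.318 with an estimated correlation.

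The numbers of probe sets that differed from 0 h were 1771 at 24 h (878 higher, 893 lower), 2492 in unruptured (1095 higher, 1397 lower) and 8332 in ruptured follicles (3700 higher, 4632 lower). Of the last, 1738 were higher and 1403 lower by at least 2-fold, so the balance turned. The count at 24 h was 1012 without 24 h replicate 1, 959 without 24 h replicate 4 and 1082 in a fit of only these 2 groups. The unruptured count was 1423 without unruptured replicate 3, 1437 without unruptured replicate 4 and 1365 with only these 2 groups.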

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

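The tests of RNA quality, macrophages, clock hour and a single ruptured array were chosen only after the result was seen; those of heat shock genes, of spread, of array number and of other splits were written before.

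Refitting other splits of the same arrays made chance an unlikely source of 7 of the 8 counts of called probe sets. The time course called 10626, and the highest of the other splits 5. The count at 12 h against 0 h was 4922 with a highest other of 4, at 24 h against 12 h 3628 with 15, in ruptured against unruptured follicles 5181 with 2, at 24 h against 0 h 1771 with 4, in unruptured follicles against 0 h 2492 with 2, and in ruptured follicles against 0 h 8332 with 755. In each of these 7, the real split was the 1 split that called as many. It was 1 of 35 splits for 24 h against 12 h and for ruptured against unruptured follicles, and 1 of 100 for the others. The splits treat follicles as interchangeable, which could not be checked, since animals and batches are not given per array. For unruptured 36 h against 24 h chance cannot be excluded, since 6 of 35 splits called as many as the real 2 and the highest other called 3.

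Of 4922 probe sets called at 12 h, 1020 were called higher and 958 lower again, in the same direction, in ruptured against unruptured follicles, and 19 in the opposite one. With the 3' minus 5' index as a covariate, 76.34% of the 1978 probe sets stayed called at both steps. Of all calls, 65.73% stayed at 12 h and 93.77% at rupture. At 12 h only replicate 3 (0.506) had an index above the 0 h range of 0.256 to 0.378, and the others had 0.331 to 0.371. The covariate rests mostly on this 1 array there, so it is a weak check. With replicate 3 left out, 77.33% of the 4922 calls at 12 h against 0 h stayed in the same direction. This argues against what the index measures as the whole source at 12 h. The index hardly differed at rupture (mean 0.326 in ruptured, 0.334 in unruptured follicles), so it could remove little there. Its actin part was lower in ruptured (0.529 to 0.638) than in unruptured arrays (0.686 to 0.830). Its GAPDH and EF1A parts were higher on average. RNA quality at rupture stays open. Macrophages and monocytes are argued against by their list's median of -0.1693 in ruptured against unruptured follicles (SD over members 0.215). The neutrophil list had a median of 0.28. Its mean per array was 4.097 to 4.731 at 12 h and 4.541 to 4.727 at 24 h, so no fall was seen between them. It was 4.297 to 5.005 in unruptured and 4.623 to 5.096 in ruptured follicles. These genes lie near the low end, so neutrophils stay open. The clock hour of collection, taken to be shared by 12 h and 36 h, is argued against by a median signed change of -0.06717 from 24 h to unruptured 36 h, at most -0.0148 without any 1 array. Stress during handling stays open too, since heat shock genes, set against this pattern only after it was seen, moved with it. Their mean per array was 8.323 to 8.784 at 0 h, 8.805 to 9.375 at 12 h and 8.1 to 8.295 at 24 h. In unruptured follicles it was 7.941 to 8.288, and in ruptured ones 8.504 to 9.393. A biological difference tied to the time after hCG and to rupture, which the groups name, stays open and was not tested.

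Few probe sets differed between 24 h and unruptured 36 h follicles. A wide spread is argued against, since the higher of the median SDs of these groups was 0.4025 against a median of 0.4348 over the other groups. Too few arrays for large changes in brighter probe sets is argued against by the 85% of simulated 4-fold changes that were called. Of 2-fold changes 52% were called, so smaller changes may have been missed. The simulation changed 100 brighter probe sets by each size and no dimmer ones, so dim probe sets and a sparser change stay open. That these follicles changed little over 12 h is a hypothesis that was not tested further.

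Of 7 immediate early genes 5 were called higher in ruptured than in unruptured follicles, with a list adjusted p = 5.74e-07, or adjusted p = 0.102 with an estimated correlation. This list was put together after the data were seen, and most of its genes are also in the fixed lists. A single array is argued against, as the lowest ruptured mean lay 0.2072 above the highest unruptured one. Stress during handling stays open, because heat shock genes had a median change of 0.8163 (SD over members 0.631), as this explanation needs. A biological difference tied to rupture, which the groups name, may act as well and was not tested apart from handling.

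In 18 of 303 sets of group values, those of named genes, array medians and the 3' minus 5' index (5.94%, where chance gives about 1 in 20) 1 array stood far from the others, by the gap to its neighbour as a share of the range. At 0 h these were INHBB in replicate 4 (lowest, share 0.646), CYP51A1 in replicate 6 (highest, 0.642), CA9 in replicate 6 (lowest, 0.649), CDKN1A in replicate 3 (lowest, 0.669), HSD11B1 in replicate 4 (highest, 0.643) and LIF in replicate 3 (lowest, 0.665). At 12 h they were PTX3 in replicate 3 (lowest, 0.86), PROK1 in replicate 1 (highest, 0.897), a second, dimmer NR4A1 probe set in replicate 2 (lowest, 0.847) and ROBO4 in replicate 3 (lowest, 0.85). At 24 h they were ROBO4 in replicate 2 (highest, 0.954) and KRT8 in replicate 4 (lowest, 0.863). In unruptured follicles they were MMP3 in replicate 3 (lowest, 0.84), a dimmer MMP1 probe set in replicate 4 (lowest, 0.849) and DUSP1 in replicate 1 (lowest, 0.837). In ruptured follicles they were MCM5 in replicate 6 (lowest, 0.885), CDKN1A in replicate 7 (highest, 0.84) and HAS2 in replicate 8 (lowest, 0.9).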

How the results depend on the processing

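The settings chosen only after the data were seen were log2 of intensity plus 16 and the 3' minus 5' index as a covariate. No named gene or gene list with a call reversed its direction. The balance of higher and lower calls turned in some settings. In ruptured follicles against 0 h it went from 3700 and 4632 to 1738 and 1403 with a 2-fold minimum and to 620 and 416 with the replicate block. A 2-fold minimum turned it also at 12 h against 0 h (870 and 854), at 24 h against 0 h (393 and 339) and in ruptured against unruptured follicles (1194 and 658). In the last 2 leaving out some single arrays turned it too, as did 1 probe set per gene at 24 h against 0 h (656 and 606). Of 141 called pairs of a named gene and a comparison, 81 lost the call under at least 1 setting. Counted by probe set, 71 calls were lost with the replicate block and 16 with the index. Most of the 71 were in ruptured against unruptured follicles, where this block is tied to rupture by construction. Subtracting array medians shifted the median log2 change by at most 0.0127 and repeated quantile normalization by at most 0.00405, and neither moved a count by over 1.5 times. Signal over background could not be judged, which limits dim probe sets. Why counts and calls moved was not tested, also not where fewer probe sets or arrays entered.

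Leaving out each array gave 9351 to 10434 calls for the time course, 3502 to 4780 for 12 h against 0 h, 2199 to 3385 for 24 h against 12 h, 0 to 5 for unruptured 36 h against 24 h, 3590 to 4599 for ruptured against unruptured, and, against 0 h, 959 to 1616 at 24 h, 1423 to 2116 in unruptured and 6975 to 8283 in ruptured follicles.

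With only the brighter probe sets the counts were 4 for unruptured 36 h against 24 h, 3070 for 24 h and 3945 for unruptured follicles against 0 h. Trend and robust moderation gave 10 for unruptured 36 h against 24 h, log2 of intensity plus 16 gave 4, and all 8 follicles of 36 h together gave 0. With 1 probe set per gene, fewer were tested and the counts were 5077 (time course), 2735 (12 h against 0 h), 2184 (24 h against 12 h), 1 (unruptured 36 h against 24 h), 2662 (ruptured against unruptured), 1553 (unruptured against 0 h) and 3633 (ruptured against 0 h). A 2-fold minimum gave 5005, 1724, 1181 and 1852 for the time course, 12 h against 0 h, 24 h against 12 h and ruptured against unruptured, and 732, 838 and 3141 against 0 h. With only the compared groups, fewer arrays entered, and the counts were 2740 (12 h against 0 h), 189 (24 h against 12 h), 0 (unruptured 36 h against 24 h), 1318 (ruptured against unruptured; 797 higher, 521 lower), 1082 (24 h against 0 h; 548 higher, 534 lower) and 1365 (unruptured against 0 h). The index as a covariate gave 2195 for 24 h against 12 h and 0 for unruptured 36 h against 24 h. Probe sets up then down numbered 202 with the 12 h arrays split and 190 with a 2-fold minimum, and those down then up 255.5 and 220.

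The replicate number as a block gave 4285 (time course), 2418 (12 h against 0 h), 2021 (24 h against 12 h), 0 (unruptured 36 h against 24 h), 34 (ruptured against unruptured; 26 higher, 8 lower), 652 (24 h against 0 h; 349 higher, 303 lower), 827 (unruptured against 0 h) and 1036 (ruptured against 0 h). Arrays with the same number had residual correlations of -0.179 to 0.173, so the numbers do not pair the follicles. Unruptured follicles carry numbers 1 to 4 and ruptured ones 5 to 8, so this block is tied to rupture by construction.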

Other observations

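The gene lists in this part and the tests on them were chosen only after the result was seen, apart from the clock score and the heat shock median in ruptured follicles, whose tests were written before, though the PER1 group means had been seen.

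Genes of ribosome biogenesis, which assemble ribosomes in the nucleolus, rose at 12 h in 10 of 22 measured cases and fell in 0, with a median log2 change of 0.53 (adjusted p = 3.15e-08, or adjusted p = 0.0848 with an estimated correlation). From 12 h to 24 h 16 fell and 0 rose, with a median of -0.91 (adjusted p = 0.00512 with an estimated correlation), and in ruptured against unruptured follicles 15 rose and 0 fell, with a median of 0.81 (adjusted p = 0.0141 with an estimated correlation). RRP9 changed by 1.08 ± 0.14 (SE), -1.55 ± 0.15 and 1.22 ± 0.15 at these steps, and NOL6 by 0.79 ± 0.15, -1.41 ± 0.16 and 1.59 ± 0.16. The list of 18 cytosolic ribosomal protein genes passed camera at none of the 4 steps (adjusted p from 0.404 to 0.676), though RPL19 rose at 12 h (1.44 ± 0.20, adjusted p = 0.000229) and RPL19 and RPS16 in ruptured follicles (1.30 ± 0.22 and 0.87 ± 0.22, adjusted p = 0.00114 and 0.0159).

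Heat shock genes moved in the same order, with 2 of 7 up at 12 h, 5 down at 24 h and 4 up in ruptured follicles, and medians of 0.50, -1.05 and 0.82 (adjusted p = 0.0127, 0.000216 and 0.00147, or adjusted p = 0.208, 0.107 and 0.145 with an estimated correlation). HSPH1 changed by 1.15 ± 0.24, -1.82 ± 0.27 and 1.66 ± 0.27. Immediate early genes had 3 of 7 up, 4 down and 5 up, with medians of 1.10, -1.27 and 1.84 (adjusted p = 0.00214, 0.000351 and 5.74e-07, or adjusted p = 0.208, 0.256 and 0.102 with an estimated correlation). All of them but IER2 are also in the fixed transcription factor or cAMP feedback lists, so this is not a separate result. From 24 h to unruptured 36 h, oxidative phosphorylation genes had a median of -0.14 and interferon-stimulated genes of 0.37, with 0 members called in limma, which had 3298 probe sets at an unadjusted p under 0.05 (adjusted p = 0.00208 and 0.0022, or adjusted p = 0.461 and 0.388 with an estimated correlation). The list of 12 circulating acute phase and antiprotease genes did not pass camera at any step (adjusted p from 0.0616 to 0.815), though SERPINA3 was called at 3 of the 4 and SERPING1 at 12 h (0.63 ± 0.16, adjusted p = 0.0166).

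The hypothesis that core clock genes follow the clock hour was tested with a score of 7 evening minus 3 morning genes. Unruptured 36 h follicles, nominally collected at the hour of the 12 h follicles, scored 0.4301 above those of 24 h, while 12 h follicles scored below 24 h (-1.66 ± 0.26 SD against -0.97 ± 0.19). Arrays of the 2 nominal clock hours differed by 0.275 (two-sided permutation p = 0.203). The hour was inferred from the hours after hCG and is fixed within each group, so this p cannot separate hour from group. Ruptured follicles, of the same nominal hour, scored -1.53 ± 0.25, near the 12 h mean, as the hypothesis needs. The unruptured follicles (-0.54 ± 0.51) lay on the side away from the 12 h follicles, which argues against the clock hour as the whole source of these scores.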
